A study of Mus musculus with 4 samples.

How the data were processed

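Gene expression was measured by RNA-seq of polyadenylated RNA from flow-sorted thymocytes of Rag1-deficient mice. There were 4 libraries, 1 each from B6 (C57BL/6) mice at 4 weeks, B6 mice at 7 weeks, NOD mice at 4 weeks and NOD mice at 6.5 weeks of age. Per the labels' protocols, messenger RNA was selected with oligo-dT beads, fragmented, copied by random priming, amplified and sequenced on a Genome Analyzer II. The protocol names no strand-specific step, so reads of a gene and of an antisense neighbour could not be told apart. The surface markers used for the sort, and whether a library came from a single mouse or a pool, are not given in the sources used here.

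Per the submitters' processing notes, reads were aligned with Bowtie 0.12.1 and the genome build was mm9, which is the C57BL/6J sequence. The read length of 32 bases comes from the names of the deposited files. Per the file headers, the authors gave each gene a length in kilobases, an RPKM value (reads per kilobase of gene model, scaled to the sequencing depth) and the fraction of its reads that mapped to more than 1 place. That deposited fraction is called the share of shared reads here. The counting program, its annotation and the way in which the authors divided shared reads among copies are not given in the sources used here. Short reads from NOD transcripts were placed on the B6 sequence, so a gene with a near-identical copy could receive reads of that copy in either strain. Values of genes with a high share of shared reads are therefore uncertain, also where the share is not printed.

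Each file listed 33114 named genes with Entrez identifiers, and between 105 and 168 regions without a gene name. Current symbols were taken by Entrez identifier from a RefSeq table of assembly GRCm38.p6, which covered 27627 genes (83.4%), and whose positions served only to order genes in a test of neighbouring calls. Of 481 entries of the gene lists, 469 were matched to a gene of the files, 18 of them through the Entrez identifier of an older symbol. Symbols are printed as the files give them, with the current symbol where it differs.

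The files hold no counts. Sequencing depth was recovered from the smallest steps between RPKM values of short genes (at most 0.6 kilobases, with RPKM times length under 0.5), as the depth at which these values best correspond to whole reads. At the chosen depth, 100%, 99.7%, 100% and 97.9% of these values lay within 0.1 reads of a whole number in the B6 week 4, B6 week 7, NOD week 4 and NOD week 6.5 libraries, where 20% are reached by chance. Read numbers behind single genes and 95% Poisson intervals, and for ratios of 2 libraries 95% exact (Clopper-Pearson) intervals, were computed from that depth. These intervals cover counting error only, since amplified reads are not independent molecules.

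The strains were compared with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), over genes with RPKM of 1 or more in at least 2 libraries, with strain as the only term, an intensity trend in the variance prior, a two-sided test and Benjamini-Hochberg adjustment at 0.05. The spread in this test came from 2 libraries per strain that differed in age. Its p-values therefore measure the spread between these 4 libraries, with 2 residual degrees of freedom. With age class as a block 1 residual degree of freedom was left, and the limma p-values then rested on the spread pooled over genes. Genes whose 2 NOD values both lay above or below both B6 values by 2-fold were counted as a description that needs no model. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists tested, with an estimated correlation beside it.

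Each of the 4 comparisons of 2 libraries rested on 1 library per group and had no replicate check, so no p-values are given for them. They are described by the log2 ratio of RPKM + 1 and by the number of genes that differ 2-fold among those with RPKM of 5 or more in either library. The same was done for the difference between the age changes of the strains. The median of a list was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and its percentile describes these libraries only. List medians are given relative to the middle of these random lists, which removes a shift common to genes of that expression level.

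The gene lists, the tests and the rule for the genes named were fixed before the data were examined. There were 23 lists: the targeted gene, sex-linked genes, progenitor genes normally silenced at T-lineage commitment, commitment and pre-TCR genes, Notch targets, double positive and beta-selection genes, DNA replication (G1/S) genes, mitotic (G2/M) genes, T-ALL (T-cell acute lymphoblastic leukaemia) oncogenes and suppressors, p53 targets, the Bcl2 family, interferon response genes, immediate early and stress genes, MHC genes, strain-polymorphic genes, housekeeping genes, ribosomal protein genes, and markers of NK and innate lymphoid cells, gamma-delta T cells, B cells, myeloid and dendritic cells, erythroid cells and thymic stroma. The first 2 were read gene by gene. The rule named the 12 called genes with the largest mean difference in each direction between the strains and the 10 genes with the largest ratio in each direction in a comparison of 2 libraries. It also named the 2 to 4 list members with the largest difference and 26 fixed genes, and left unannotated gene models unnamed. One of the fixed genes is not reported here.

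Alternatives were pseudocounts of 0.1 and 5, no filter or a filter at RPKM 5, TMM rescaling (trims of 30% and 5%), quantile normalization, age class as a block, no variance trend, and leaving out each library in turn. Chosen after seeing the data were a restriction to genes with under 10% shared reads, a removal of the trend of each library with GC content and length, TMM rescaling together with the age block, and leaving out libraries for the lists and the non-overlap counts. GC content came from the longest GENCODE transcript of a gene, and the trends were fitted by lowess with a fraction of 0.3. Where fewer than 80.0% of a set of genes had a GC value, the check on that set is void. The strain test was tested on simulated data with 200 genes changed among 12413: at a log2 change of 1 it recovered 60.0%, at 2 and at 3 it recovered 100%, and 5.88% of its calls were false. The simulated noise was independent between genes, had a spread set by expression level and held no library-wide shift. These rates therefore need not hold for the real libraries. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6 was used for the remaining steps. Regions without a gene name entered no comparison.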

Results

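Thymocytes of Rag1-deficient mice were profiled by RNA-seq in B6 and NOD, an inbred strain prone to autoimmune diabetes. Rag1 encodes a subunit of the recombinase that assembles antigen receptor genes, and without it thymocytes are held before the CD4 CD8 double positive stage. The series concerns the failure of this early checkpoint and the onset of leukaemia in Rag1-deficient NOD mice. It held 1 library per strain and age: B6 at 4 and 7 weeks and NOD at 4 and 6.5 weeks. Each library had no replicate of its strain and age, and the labels do not say whether it came from 1 animal or a pool. The recovered depth was 17040000 reads for B6 week 4, 21220000 for B6 week 7, 17260000 for NOD week 4 and 24090000 for NOD week 6.5, of which 11424388, 11156869, 10939290 and 14795028 fell in the listed genes and regions. Between 11841 and 12278 genes had RPKM of 1 or more in a library.

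Rag1 RNA was present in every library, with RPKM of 132.9 in B6 week 4, 108.0 in B6 week 7, 121.4 in NOD week 4 and 91.7 in NOD week 6.5. The labels do not say which part of the gene was removed, so this level does not check the knockout. In the same order of libraries, the RPKM of Rag2, the partner subunit, was 30.7, 32.1, 30.4 and 20.9. The libraries had a double negative profile: Il2ra, the interleukin-2 receptor alpha chain of this stage, was at 460.8, 422.4, 491.9 and 531.1, and Ptcra, the pre-T-cell receptor chain, at 279.1, 173.1, 317.7 and 224.4. Cd3e was at 314.4, 193.7, 319.7 and 280.3, and the commitment factors Bcl11b at 101.9, 77.4, 98.8 and 82.9, Tcf7 at 284.0, 159.8, 280.6 and 290.3 and Gata3 at 20.8, 14.8, 23.2 and 19.2. Notch1 was at 252.1, 139.5, 316.8 and 249.5, its target Hes1 at 86.7, 69.1, 70.3 and 61.0, and Myc at 76.0, 43.5, 80.7 and 65.5. Cd4 was low at 1.25, 0.63, 1.46 and 2.78, and Cd8a at 0.06, 0.03, 0.05 and 0.16. The stem cell transcription factor gene Tal1 was at 0.19, 0.06, 0.16 and 0.18, the innate lymphoid regulator Zbtb16 at 0.03, 0.06, 0.27 and 0.79, and Id2 at 7.33, 5.36, 4.64 and 3.5.

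The sex-linked genes differed between libraries. Xist, transcribed from the inactive X chromosome, was at RPKM 100.0, 119.8, 20.2 and 77.9 in the same order, and the Y-linked gene Ddx3y at 5.20, 9.85, 16.7 and 6.42. Transcripts of both sexes were thus found in every library, in different proportions, with the lowest Xist and the highest Ddx3y in NOD week 4. Changes of Y-linked genes between libraries therefore cannot be told apart from a different mix of the sexes. The effect of that mix on other genes was not tested.

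The strain comparison asked which transcripts differed between NOD and B6 thymocytes, with the 2 ages of a strain as its libraries. MHC class I genes outside the classical loci were among those that rose in NOD. H2-T3, the thymus leukaemia antigen, had a mean RPKM of 140.0 ± 36.1 in NOD and 0.080 ± 0.0424 in B6 (SD, n = 2), H2-T10 of 175 ± 8.16 against 8.89 ± 0.735, H2-Bl of 38.3 ± 3.10 against 0.185 ± 0.0495, and H2-gs17 (Gm8909) of 14.3 ± 1.53 against 0.665 ± 0.106. Ifi202b, an interferon-inducible gene of the HIN-200 family, was at 46.5 ± 4.41 in NOD and listed at 0 in both B6 libraries. Epha2, an Eph receptor tyrosine kinase, was at 24.6 ± 5.37 against 0.465 ± 0.0778, the oestrogen receptor gene Esr2 at 14.3 ± 2.59 against 0.495 ± 0.134, the Ras GTPase-activating gene Rasa4 at 45.9 ± 6.51 against 3.75 ± 0.834, and the junction scaffold gene Mllt4 (Afdn) at 76.0 ± 9.08 against 7.20 ± 0.417. Ttll2 (Gm11166), Vcp-ps (Vcp-rs) and Tmem98 completed the 12 named genes higher in NOD, with log2 differences of 4.18, 2.90 and 2.69. The share of shared reads reached 77% for H2-T3, 63% for H2-T10, 57% for H2-Bl, 93% for H2-gs17, 100% for Ttll2 and 87% for Vcp-ps, which leaves these values uncertain. Adjusted p values of these 12 genes in limma ran from 5.98e-05 to 0.000719.

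Among the genes lower in NOD, Ndg1 (Khdc1a) had a mean RPKM of 2.07 ± 1.58 in NOD and 134.5 ± 45.8 in B6 (SD, n = 2), Trim12 (Trim12a), of the TRIM antiviral family, 0.555 ± 0.0212 against 25.8 ± 3.80, and the surface antigen gene Ly6c (Ly6c1) 0.145 ± 0.00707 against 15.5 ± 1.32. Capg, an actin-capping protein gene, was at 0.185 ± 0.0495 against 15.0 ± 4.10, the kinase gene Camk2a at 0.995 ± 0.0636 against 18.0 ± 2.75, and Art4, of the ADP-ribosyltransferase family, at 0.495 ± 0.332 against 12.2 ± 0.771. The peptide transporter gene Slc15a2 was at 5.78 and 16.3 in B6 and listed at 0 in both NOD libraries. Tpd52 was lower by a log2 difference of -4.05. The ribosomal protein genes Rpl29, Rpl35a, Rps18 and Rpl21 were lower by -4.52, -3.85, -3.75 and -3.68, each with a share of shared reads of 75% or more in some library. That share reached 74% for Ndg1, 100% for Trim12, 53% for Ly6c and 42% for Tpd52. Adjusted p values of these 12 genes in limma ran from 0.000124 to 0.00318.

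In all, limma called 345 genes higher and 197 lower in NOD of 12413 tested, and 1574 had an unadjusted p under 0.05. All of the called genes had both NOD values on one side of both B6 values, and 291 of the higher and 168 of the lower genes differed 2-fold. Shared reads were common among them: 47.8% of the higher and 37.6% of the lower genes had a share of 50% or more in some library, against 20.1% of all genes tested. With genes of under 10% shared reads only, 121 were higher and 70 lower of 8525. TMM rescaling of all 12413 genes gave 365 higher and 259 lower, and quantile normalization 353 and 275, so the excess of higher genes was smaller with these scalings. Without B6 week 4 the median log2 difference of the tested genes was 0.25, against 0.096 with all 4 libraries. An age block gave 665 and 340, on 1 residual degree of freedom and with the spread pooled over genes. No filter on low values gave 82 and 40. With it Ndg1, Rpl29, Rps18, Slc15a2, Nnt, Rps6kl1, Tcte2, Adam11, Tsga2, Ctla4 and Dapk1 were no longer called. Removal of the GC and length trend gave 237 higher and 271 lower of 10116, where 54.8% of the higher and 69.0% of the lower calls had a GC value, so that this check is void for the called set.

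Genes with under 10% shared reads in every library hold the differences that rest mainly on reads of a single place. After Epha2, Esr2, Rasa4, Mllt4 and Tmem98, those highest in NOD were the kinase-like gene Rps6kl1 at a mean RPKM of 77.7 ± 24.8 against 11.6 ± 3.78 in B6 (SD, n = 2), Trim16 at 18.6 ± 2.45 against 2.57 ± 0.339, Adam11 at 13.6 ± 2.21 against 1.66 ± 1.05, and the calcium channel gene Ryr2 at 4.79 ± 1.08 against 0.020 ± 0.0141. Tcte2, Inppl1, a phosphoinositide phosphatase gene, and Tsga2 (Rsph1) followed with log2 differences of 2.56, 2.42 and 2.37. After Capg, Slc15a2, Camk2a and Art4, those lowest were Eps8l1 with a log2 difference of -3.07, the vesicle transport genes Rab27a and Rab6b with -2.92 and -2.81, the inhibitory receptor gene Ctla4 with -2.58, Dapk1, a death-associated kinase, with -2.54, the glutathione reductase gene Gsr with -2.45, Emb with -2.40, and Dtx4, of the Deltex family in the Notch pathway, with -2.37. The limma adjusted p values of these 15 genes ran from 0.000380 to 0.00435, and this selection was made after the data were seen.

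**Figure D1:**
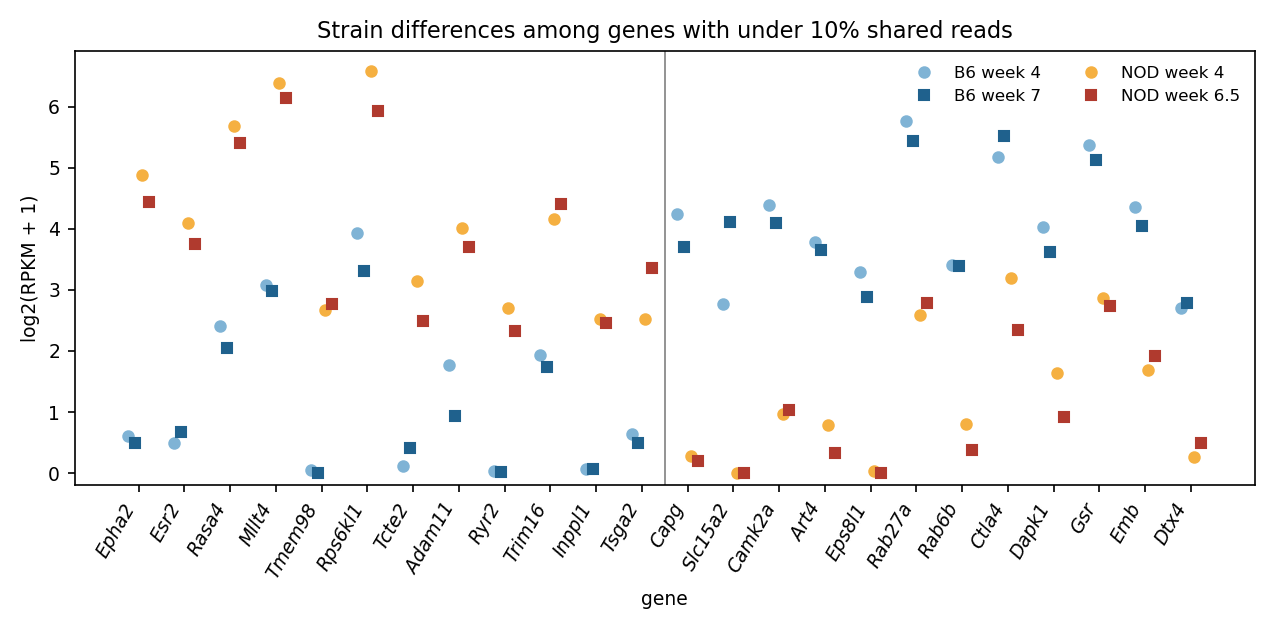
Expression as log2(RPKM + 1) in each of the 4 libraries (points) for the called genes with under 10% shared reads that differed most between the strains, 12 higher in NOD on the left and 12 lower on the right. In each gene the 2 NOD points lie on one side of the 2 B6 points.

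Among the gene lists, members of the MHC list moved both ways: 7 of 25 rose and 4 fell in NOD, and 8 and 5 when adjusted over the list alone. H2-T3, H2-T10 and H2-Q2 rose by log2 differences of 7.005, 4.16 and 2.56, while H2-K1, a classical class I gene, fell by 2.25. The median of this list was -0.05, its mean 0.44 and camera's direction up, with an adjusted p of 0.742. With an age block, which left 1 residual degree of freedom, camera's adjusted p was 0.00778. The strain-polymorphic list was lower in camera (adjusted p = 8.21e-05, and adjusted p = 0.953 with an estimated correlation), with 1 member higher and 4 lower of 11, and 1 and 5 when adjusted over the list alone. Its called members were Ly6c at -3.85, Ly6a, the Sca-1 antigen, at -2.94, Ctla4 at -2.58 and Slamf1, a lymphocyte surface receptor, at -1.69, and Nnt, a mitochondrial transhydrogenase gene partly deleted in C57BL/6J, was higher by 1.24. The RPKM of Nnt was 10.9 and 7.79 in B6 and 23.97 and 22.4 in NOD. Ribosomal protein genes were lower in camera (adjusted p = 1.14e-07, and adjusted p = 0.965 with an estimated correlation), with 0 higher and 5 lower of 40, both over all genes and adjusted over the list alone. Those 5 were Rps18, Rps24, Rpl3, Rps28 and Rpl30 with log2 differences of -3.75, -2.90, -2.30, -1.99 and -1.42 and shares of shared reads of 89% or more. Interferon response genes were lower in camera (adjusted p = 0.00231, and adjusted p = 0.953 with an estimated correlation), with Mx2, an antiviral GTPase gene, higher by 0.98 and Rsad2, the viperin gene, lower by -0.83 of 22 members, and 1 and 3 when adjusted over the list alone. Without B6 week 7 the interferon list had a camera adjusted p of 0.169. With an estimated correlation none of the 21 lists was called and none had an unadjusted p under 0.05.

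Other lists held few called genes. In limma, Dtx4 fell by 2.37 and Heyl, a Notch-responsive repressor gene, rose by 1.44 among 16 Notch targets, Aqp11 fell by 1.27 and Egr1, an immediate early transcription factor, by 1.23 among 17 double positive and beta-selection genes, and the B-cell coreceptor gene Cd72 fell by 0.96 among 7 B-cell genes. Egr1 was also the single call among 12 immediate early genes. Gapdh, a glycolytic enzyme gene with many pseudogenes, fell by 2.87 among 15 housekeeping genes, with a share of shared reads of up to 66%. In limma none of the 134 tested members of the other 12 lists was called, and 8 had an unadjusted p under 0.05. These lists were the progenitor, commitment, G1/S, G2/M, T-ALL, p53, Bcl2 family, NK, gamma-delta, myeloid, erythroid and stromal genes. Adjusted over the list alone, these counts were the same except for 2 lower among housekeeping genes and 1 higher among gamma-delta genes.

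Counted without a model, 228 genes had both NOD values 2-fold above both B6 values and 116 had both 2-fold below. Regardless of size, 43.9% of the genes separated the strains, against 33.3% by chance. Without NOD week 4 this was 58.7% and without NOD week 6.5 63.1%, both under the 66.7% of chance with 3 libraries, and without B6 week 4 it was 88.0% and without B6 week 7 77.6%. With genes of under 10% shared reads only, the counts were 93 and 54. Comparisons at a single age set 1 library against 1, so they had no replicate check and compare libraries rather than conditions. At week 4, 198 genes were 2-fold higher and 181 lower in NOD than in B6 of 8863, and between NOD week 6.5 and B6 week 7, 510 were higher and 139 lower of 8634. Over the 9028 genes with RPKM of 5 or more in any of the 4 libraries, 209 were higher at week 4 and 525 at the later age, with 178 in common where 12.2 would be by independence, and 188 and 148 were lower, with 106 in common where 3.08 would be. The later comparison changed with scaling, to 291 higher and 216 lower with TMM and 138 and 119 with the GC and length trend removed, where 76.1% and 71.2% of its genes had a GC value, so that this last check is void.

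At week 4, the genes furthest apart were largely those of the strain comparison, of which these 2 libraries are a part. H2-T3, H2-Bl, H2-T10, H2-gs17, Epha2, Esr2, Mllt4, Rasa4, Ttll2 and Ifi202b were highest in NOD, and Rpl29, Ndg1, Rpl35a, Rps18, Capg, Trim12, Ly6c, Tpd52, Rpl21 and Camk2a lowest. Mitotic genes were lower in NOD by a relative median of -0.34 (percentile 0) and G1/S genes by -0.23 (percentile 0.070), with Kif11, a spindle motor gene, at RPKM 10.8 against 21.3 and the replication clamp gene Pcna at 150.1 against 230.7. NK and innate lymphoid markers were lower by -0.52 (percentile 0.040), with Nkg7 at 32.1 against 58.0, progenitor genes by -0.34 (percentile 0.46), and immediate early genes by -0.35 (percentile 0.020), with Fos at 0.67 against 3.53. Commitment genes were higher by 0.20 (percentile 99.7, and 96.7 for members with under 10% shared reads), with the transcription factor gene Lef1 at 107.9 against 62.0. Double positive and beta-selection genes were lower by -0.24 (percentile 0.37), with Aqp11 at 78.4 against 179, B-cell genes by -0.33 (percentile 0.89), with Igh-6 (Ighm) at 11.4 against 33.8, ribosomal protein genes by -0.29 (percentile 0) and strain-polymorphic genes by -0.56 (percentile 0.010). In each comparison of 2 libraries, too few ribosomal and erythroid list members had under 10% shared reads for these lists to be placed on such members alone. Interferon response genes lay at -0.13 (percentile 3.23, and 0.33 with the GC and length trend removed).

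Between NOD week 6.5 and B6 week 7, Sprn and Dlk1 joined H2-T3, Ifi202b, H2-Bl, H2-T10, Epha2, Ttll2, Rasa4 and Mllt4 among the 10 genes highest in NOD. The 10 lowest were Ndg1, Trim12, Tpd52, Slc15a2, Rpl29, Ly6c, Rpl21, Rpl35a, Capg and Rps18. Progenitor genes were higher by a relative median of 0.996 (percentile 100), G1/S genes by 0.71 (percentile 100) and mitotic genes by 0.28 (percentile 99.5, and 96.1 among members with under 10% shared reads). Interferon response genes were lower by -0.51 (percentile 0), with Ifi44 at RPKM 1.56 against 4.61 and the guanylate-binding gene Gbp2 at 11.0 against 21.4. Strain-polymorphic genes were lower by -0.47 (percentile 0.29), ribosomal protein genes by -0.22 (percentile 1.72) and erythroid genes by -0.73 (percentile 0.24). With the GC and length trend removed, the B-cell, MHC, Bcl2 family, immediate early and housekeeping lists also left the central 95%, at percentiles 0.495, 0.010, 2.46, 0.20 and 99.0.

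The age comparison in NOD asked what differed between thymocytes at 4 and at 6.5 weeks. Progenitor genes that are normally silenced at T-lineage commitment were higher at week 6.5. Lyl1, a basic helix-loop-helix leukaemia oncogene, was at RPKM 8.39 against 0.90 (9.32-fold, 95% interval 6.34 to 14.2), Hhex, a homeobox gene of early progenitors, at 6.5 against 0.68 (9.56-fold, 6.12 to 15.7), Lmo2, the LIM-domain partner of Lyl1 and Tal1, at 5 against 0.44 (11.4-fold, 6.49 to 21.7), and the stem cell factor receptor gene Kit at 19.4 against 6.33 (3.06-fold, 2.79 to 3.36). Mef2c was 4.04-fold higher (3.05 to 5.43) and Nfe2 2.86-fold (2.54 to 3.24). Sfpi1 (Spi1, the PU.1 gene) was at 1.44 against 0.30 (4.80-fold, 2.14 to 12.7). Not all early genes went up: Bcl11a was at 1.44 against 2.30 (0.626-fold, 0.477 to 0.821) and Mycn at 6.68 against 8.38. Of the 10 measured list members 6 were 2-fold higher and 0 lower, and the list median was 1.49 above that of matched random lists (percentile 100). NOD week 4 was itself low for this list, by -0.34 relative to B6 week 4 (percentile 0.46). Lyl1 was at 3.84 in B6 week 4 and 1.47 in B6 week 7.

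**Figure D2:**
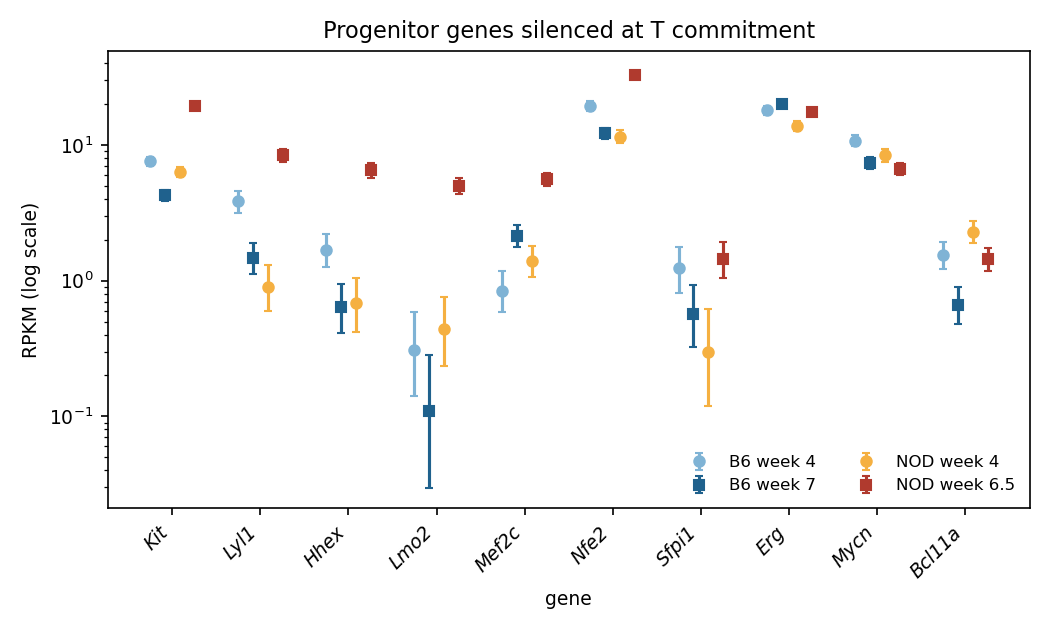
RPKM on a log axis of progenitor genes in each of the 4 libraries, with bars for 95% Poisson intervals of the counting error. Kit, Lyl1, Hhex and Lmo2 are highest in the NOD week 6.5 library, while Bcl11a is not.

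Ranked by the log2 ratio of RPKM + 1, the 10 highest genes at NOD week 6.5 were none of these. By plain RPKM ratio, Lmo2, Hhex and Lyl1 lay above Cpa3 (8.17-fold), Gpr97 (7.71-fold) and Mt1 (6.56-fold), which are among the 10. Sprn, the shadow of prion protein gene, was at RPKM 12.03 against 0.15 (80.2-fold, 40.8 to 184), Dlk1, a Notch ligand-like gene, at 10.2 against 0.25 (40.7-fold, 19.6 to 101), the tight junction gene Cldn2 at 8.74 against 0.36 (24.3-fold, 15.4 to 40.7), and the gut-homing integrin gene Itgb7 at 18.0 against 1.41 (12.8-fold, 9.93 to 16.7). Cpa3, a carboxypeptidase gene of mast cells and early progenitors, was at 43.6 against 5.34. Its level in NOD week 4 was the lowest, with 19.4 in B6 week 4 and 18.9 in B6 week 7. Klf2, a regulator of lymphocyte trafficking, was at 11.0 against 0.87, and the adhesion receptor gene Gpr97 (Adgrg3) at 21.6 against 2.80. The metallothionein genes Mt2 and Mt1 were at 36.4 against 3.75 and 62.5 against 9.53. Gzmb, encoding granzyme B, was at 7.67 against 0.41.

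Genes on the gamma-delta list were higher as well. The receptor genes Trdc and Tcrg-C1 of that list were not matched, so it cannot show the presence of gamma-delta T cells. All 8 measured gamma-delta genes lay above the middle of matched random lists (relative median 0.50, percentile 100), led by Gzmb and E430002D04Rik (Cd163l1, a scavenger receptor gene) at RPKM 68.25 against 12.02 (5.68-fold, 5.25 to 6.15). The NK and innate lymphoid list was 0.47 above (percentile 100), with 5 of 8 members above the middle and 3 below: Cd7 was at 6.29 against 0.83, while Gzma was at 53.99 against 75.8 and Id2 at 3.5 against 4.64. Gzmb is in both lists. Among double positive and beta-selection genes (relative median 0.14, percentile 98.9), Cd5, Cd53 and Cd6, surface molecules of maturing T cells, were at 3.31 against 0.64, 41.7 against 16.2 and 6.04 against 2.46. The B-cell list was higher by 0.20 (percentile 98.4, and 91.6 with the GC and length trend removed), with Igh-6 (Ighm) at 29.8 against 11.4. The T-ALL list was higher by 0.11 (percentile 99.0, and 80.3 among members with under 10% shared reads), and its leading members, Lyl1, Lmo2, Kit and Mef2c, are those of the progenitor list. Commitment genes were lower by -0.11 (percentile 0.84, and 4.615 among members with under 10% shared reads), with Ptcra at 224.4 against 317.7, although Cd2 was at 3.45 against 0.86 and Zap70 at 18.0 against 10.5. Interferon response genes were lower by -0.14 (percentile 0.17), with Oasl2 at 5.92 against 10.7 and the master regulator gene Irf7 at 6.52 against 10.2. Replication genes were slightly higher, by 0.21 (percentile 100), with Cdc6 at 11.4 against 7.76.

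Genes lower at NOD week 6.5 included those of red cells and of the Y chromosome. Haemoglobin genes Hba-a1 and Hbb-b1 were at RPKM 4.12 against 29.6 and 1.72 against 13.4, with the erythroid list at -1.47 (percentile 0). The shares of shared reads of Hba-a1 and Hbb-b1 reached 98% and 92%, which leaves these values uncertain. The imprinted gene H19 was at 116 against 388, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Jarid1d (Kdm5d) at 6.42 against 16.7, 4.56 against 11.4, 15.0 against 34.3 and 4.85 against 11.4. The small RNA genes Rnu35b (Snord35b) and Rmrp were at 2.08 against 8.11 and 2.72 against 8.42, on 5.01 and 18.0 reads in the older library, and Erh, with 99% shared reads, at 41.1 against 92.6. In all, 59 genes were 2-fold higher and 12 lower at week 6.5 of 8646, and the 49 and 10 of these with a GC value all stayed 2-fold apart with the GC and length trend removed. The NOD week 6.5 file listed some shared reads for 96.6% of its genes with RPKM of 1 or more, against 43.1% to 44.1% in the other files, and with genes of under 10% shared reads the counts were 47 and 7. A pseudocount of 5 gave 30 and 5, and no filter gave 90 higher.

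The stromal list was also higher in this comparison, by 0.27 (percentile 98.4) on 4 members, with 2 above the middle of the random lists and 2 below: Pdgfrb, a fibroblast and pericyte receptor gene, was at RPKM 6.33 against 1.22, while Tacstd1 was at 13.2 against 26.8. The remaining lists lay inside the central 95% of random lists. Relative medians were 0.03 for Notch targets (percentile 70.9), 0.05 for mitotic genes (percentile 88.2, and 99.0 among members with under 10% shared reads), -0.08 for p53 targets (percentile 9.13), -0.06 for the Bcl2 family (percentile 15.2), 0.05 for immediate early genes (percentile 79.8), 0.03 for MHC genes (percentile 74.9), 0.01 for ribosomal proteins (percentile 63.8), 0.13 for strain-polymorphic genes (percentile 96.5), 0.10 for housekeeping genes (percentile 97.2, and 98.2 among members with under 10% shared reads) and -0.14 for myeloid genes (percentile 8.19). Within these lists, Cdkn1a, the p21 cell cycle inhibitor gene, was at 31.9 against 55.1, Trib2, a Notch target, at 3.24 against 0.66 and Cd244, a lymphocyte receptor gene, at 4.44 against 1.11.

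The age comparison in B6 asked what differed between 4 and 7 weeks in the strain that served as reference. Cell cycle genes were lower at week 7. Among replication genes, the licensing factor gene Cdt1 was at RPKM 8.92 against 32.8 (0.272-fold, 95% interval 0.243 to 0.304), and the helicase genes Mcm5, Mcm3 and Mcm2 were at 25.2 against 69.5, 30.1 against 77.7 and 30.8 against 77.2. Among mitotic genes, the kinase genes Aurkb and Plk1 were at 5.87 against 19.99 and 4.83 against 16.4, and Cdc20, an activator of the anaphase-promoting complex, at 9.19 against 29.9. Of 20 replication genes 10 were 2-fold lower and 0 higher, and of 22 mitotic genes 8 and 0. Their medians were -0.62 and -0.56 relative to matched random lists (percentile 0 for both), and -0.49 and -0.61 with the GC and length trend removed (percentile 0 for both).

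**Figure D3:**
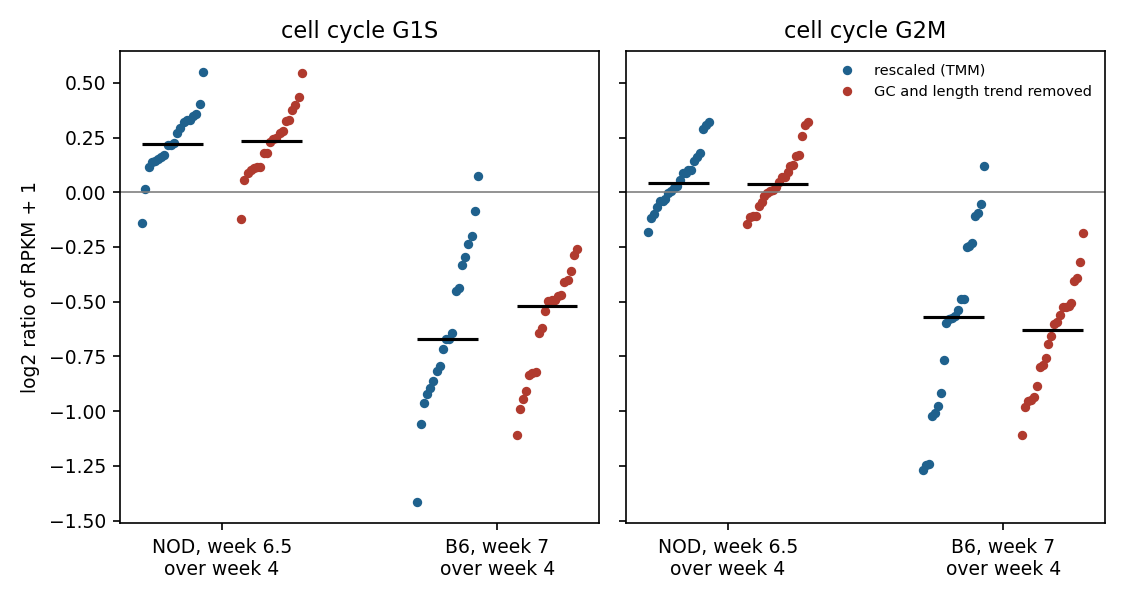
Log2 ratio of the later to the earlier age in NOD and in B6 for each member (points) of the replication list (left) and the mitotic list (right), with TMM-rescaled values in blue, values after removal of the GC and length trend in red and black lines at the medians. In B6 most members lie below 0 in both versions, and in NOD most replication genes lie above 0.

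The 10 lowest genes at B6 week 7 included Cdt1, Pkmyt1, a kinase that restrains mitotic entry (RPKM 3.26 against 12.8), the tubulin gene Tuba1b (80.2 against 344.3), the linker histone gene H1fx (H1f10, 0.93 against 7.46) and the histone genes Hist1h2an (H2ac22), Hist1h2ae (H2ac8) and Hist1h2ai (H2ac13) at 9.33 against 38.5, 1.81 against 9.16 and 4.67 against 19.2. Tuba1b and these 3 histone genes had shares of shared reads of 85% or more. Mospd3, Rpl36 and Hba-a1 were at 21.5 against 75.5, 95.2 against 319.7 and 5.92 against 23.4, with shares of shared reads of 48%, 100% and 100%. With the GC and length trend removed all 10 were less low. The log2 ratio of Cdt1 went from -1.77 to -1.11 and that of H1fx from -2.13 to -1.20. The highest were the MHC genes H2-Q6 (13.5 against 4.60) and H2-Q8 (14.2 against 7.03), Slc15a2 (16.3 against 5.78), Mt1 (6.69 against 2.78), Rmrp (15.1 against 7.46), the mitochondrial leucyl-tRNA synthetase gene Lars2 (755.1 against 400.7), the Y-linked Eif2s3y (16.8 against 8.80) and Ddx3y (9.85 against 5.20), the inflammatory caspase gene Casp1 (13.1 against 7.33) and Samd9l (11.6 against 6.45). H2-Q6, H2-Q8 and Lars2 had shares of shared reads of 52%, 95% and 85%.

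The B6 week 7 library was lower over most genes. Of its recovered depth 52.6% fell in the listed genes and regions, against 67.0% in B6 week 4. RPKM is scaled to depth, so this smaller part lowers the listed genes together. Of 8582 genes 12 were 2-fold higher and 328 lower, and the median log2 ratio was -0.38. With TMM rescaling the counts were 67 and 61, and with the GC and length trend removed 9 and 20. The log2 ratio fell with the GC content of the gene across 7654 genes, which are not independent replicates (Pearson r -0.704, Spearman rho -0.728), while r was -0.134 in the NOD age comparison and 0.479 between NOD week 6.5 and B6 week 7. Of the 328 lower genes, 90.2% had a GC value and 20 stayed 2-fold lower after that removal, and of the 12 higher genes 25% had one, so that the check is void for them.

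**Figure D4:**
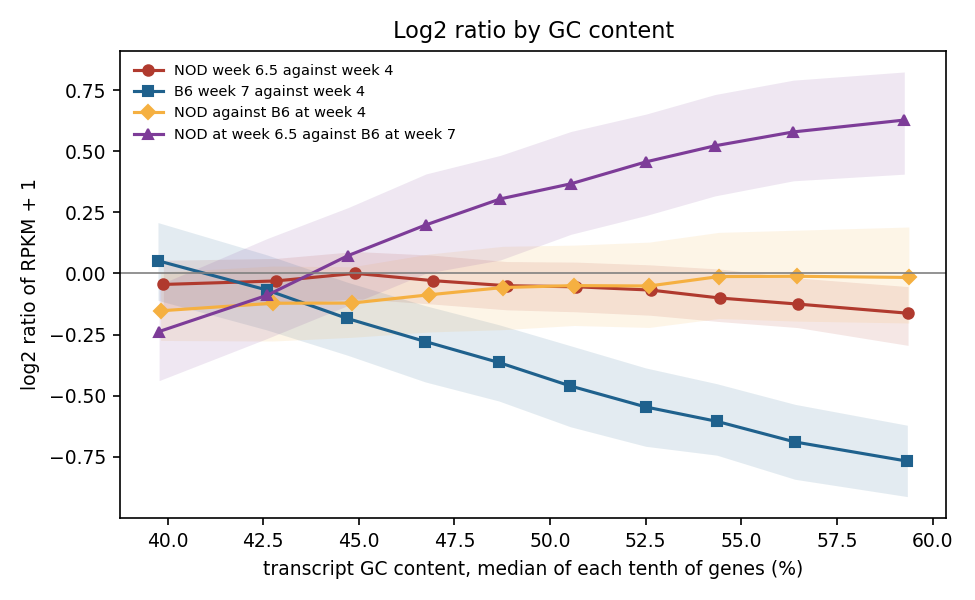
Median log2 ratio (lines, shading from the lower to the upper quartile) of genes in 10 groups of rising GC content, for each of the 4 comparisons of 2 libraries. The ratio of B6 week 7 to week 4 goes from 0.05 in the group of lowest GC to -0.77 in that of highest GC.

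Among the other lists in the B6 age comparison, progenitor genes were lower by -0.36 (percentile 0.32) and immediate early genes by -0.33 (percentile 0.50), but both lay inside the central 95% with the GC and length trend removed (percentiles 7.87 and 9.32). In the progenitor list Lyl1 was at RPKM 1.47 against 3.84 and Mef2c at 2.14 against 0.84, and among immediate early genes Fos was at 0.76 against 3.53. Notch targets were lower by -0.24 (percentile 2.46, and 29.9 after the removal), with Notch1 at 139.5 against 252.1. Erythroid genes were lower by -0.65 (percentile 0.050) on 4 members, of which 75% had a GC value, so that the check is void for them, and strain-polymorphic genes higher by 0.29 (percentile 98.2, and 76.1 after the removal). Relative medians of the others ran from -0.16 for housekeeping genes (percentile 10.7) to 0.23 for gamma-delta genes (percentile 94.8), with interferon response genes at 0.19 (percentile 97.2). With the GC and length trend removed, the gamma-delta, MHC and interferon lists lay at percentiles 99.9, 99.2 and 98.7.

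The difference between the age changes asks whether NOD and B6 thymocytes changed alike. It has no residual degree of freedom in 4 libraries and was not tested. The progenitor genes Lyl1, Hhex, Lmo2 and Kit had log2 differences of 3.28, 2.87, 2.30 and 2.19 between the age change in NOD and that in B6, and 6 of 10 list members were 2-fold higher in it, with a relative median of 1.53 (percentile 100). Sprn, Gpr97, Itgb7, Dlk1, Cldn2, Cpa3, Klf2 and Mdga1, with 3.39, 3.20, 3.13, 3.12, 3.01, 2.85, 2.66 and 2.61, were the other genes at its top. Replication and mitotic genes stood at 0.81 and 0.67 (percentile 100 for both), with Cdt1 at 2.04 and Aurkb at 1.72, and interferon response genes at -0.32 (percentile 0.14), with Ifi44 at -1.19. NK and gamma-delta genes stood at 0.50 and 0.36 (percentiles 99.7 and 98.35), erythroid genes at -0.75 (percentile 0.060) and immediate early genes at 0.26 (percentile 97.7). With the GC and length trend removed, the gamma-delta and immediate early lists were inside the central 95% (percentiles 97.4 and 75.7), and the MHC, p53, myeloid and housekeeping lists left it (percentiles 0.060, 1.01, 2.12 and 99.4). At the bottom were Rmrp, Rnu35b, Ddx3y, Eif2s3y, Ndg1 and Uty with -2.27, -2.08, -2.06, -2.00, -1.80 and -1.60, and H2-Q6, Jarid1d, Slc15a2 and Ctla4 with -1.53, -1.43, -1.35 and -1.20. In all, 457 genes were 2-fold higher and 34 lower of 9028. These were 176 and 106 with TMM rescaling and 105 and 35 with the GC and length trend removed, where 84.9% of the higher and 50% of the lower genes had a GC value, so that the check is void for the lower genes.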

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

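In this part, the tests on a larger share of early progenitors and on 1 scaling factor were chosen only after the results they address had been seen. The following values differed in direction between the age changes of the 2 strains or came from data that the comparisons did not use, and no difference was tested, since each rests on 1 library per strain and age. Replication (G1/S) genes lay 0.21 above matched random lists in the NOD age change and at -0.62 in that of B6. Progenitor genes lay 1.49 above in NOD and at -0.36 in B6. The TMM-rescaled log2 age change of Lyl1 was 2.32 in NOD and -0.71 in B6, that of Hhex 2.17 and -0.53, and that of the Y-linked gene Ddx3y -1.195 and 1.15. The change of Ddx3y cannot be told apart from a different mix of the sexes in these libraries. Of the genes and regions with RPKM of 1 or more in the NOD week 6.5 file, 96.6% held shared reads. The unannotated gene model LOC672857 held 3.97% of the summed reads in B6 week 7. Regions without a gene name held 0.280% of the summed reads in B6 week 4, 0.528% in B6 week 7, 0.412% in NOD week 4 and 0.432% in NOD week 6.5.

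Progenitor genes were higher in the NOD week 6.5 library, with Lyl1, Hhex, Lmo2 and Kit at least 3.06-fold above NOD week 4. Mast cells, which express Kit and Cpa3, are argued against, since 6 mast cell genes together rose by 0.07 RPKM where Cpa3 alone was higher by 38.3. A different handling of multiply mapping reads in that file is argued against as well, since the annotated genes that were 2-fold higher had a median of 3% shared reads. Whether the sort held a larger share of early progenitors cannot be told apart from a change within the cells: 2 early genes (Bcl11a and Mycn) had ratio intervals below 3.06, those of Sfpi1 and Cd34 reached above it, and Flt3, Meis1 and Hoxa9 had at most 2.95 reads and could not be tested. A biological age difference in NOD thymocytes stays open, since it was not tested beyond 1 library per age.

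Cell cycle genes were lower in the B6 week 7 library, in which genes of high GC content were also lower. A GC-dependent loss as the whole cause is argued against, since the mitotic list stayed at percentile 0 of matched random lists with the GC and length trend removed. A single scaling factor, as from ribosomal RNA carry-over, is argued against by the mitotic list median of -0.56 relative to matched random lists, which such a factor would leave at 0. Which of the B6 libraries differs is not settled either. At week 4 mitotic and G1/S genes were lower in NOD than in B6, by relative medians of -0.34 and -0.23. At the later age they were higher in NOD, by 0.28 and 0.71. A biological age difference in B6 thymocytes and a different composition of the sorted cells stay open, since neither was tested. So does a technical difference of either B6 library other than GC-dependent loss or a single scaling factor.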

How the results depend on the processing

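No gene called between the strains and named in the text changed sign, but other results did turn. In camera the G1/S list went up in the main test without a call and down without B6 week 7 (adjusted p = 0.0320), where the G2/M list was called as well, also down (adjusted p = 2.66e-05, against 0.742 in the main test), and the MHC list, also not called, went up in the main test and down with the GC and length trend removed. The log2 age change of Il2ra in B6 went from -0.13 to 0.26 with TMM rescaling. Except where a setting tests fewer genes or libraries by construction, the cause was not tested. Of the values for single named genes in the comparisons of 2 libraries, 237 moved beyond their counting interval and 469 did not. In the strain test, 844 single values kept their direction and call, 14 became called and 13 were no longer called. The counts below are those that moved by over 1.5 times, and 65 other counts did not.

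With a pseudocount of 0.1, 19 genes were lower at NOD week 6.5 than at week 4 and 499 lower at B6 week 7 than at week 4, 55 were lower in the difference of the age changes, and 356 and 184 had both NOD libraries 2-fold above and below both B6 libraries. With a pseudocount of 5, 30 were higher and 5 lower in the NOD age comparison, 1 and 112 in that of B6, 111 and 100 in NOD against B6 at week 4, 221 and 92 at the later age, 186 and 13 in the difference of the age changes, and 81 and 64 lay above and below both B6 libraries. Without a filter on low values, 90 were higher in the NOD age comparison, 27 higher in that of B6, 326 higher and 273 lower in NOD against B6 at week 4, 212 lower at the later age, and 66 lower in the difference of the age changes, and the strain test called 82 higher and 40 lower. With a filter at RPKM 5 it called 152 and 87.

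With TMM rescaling, 67 were higher and 61 lower in the B6 age comparison, 291 and 216 in NOD against B6 at the later age and 176 and 106 in the difference of the age changes. With quantile normalization these were 56 and 58, 297 and 213, and 169 and 104. With age class as a block the strain test called 665 higher and 340 lower, and with TMM rescaling and the block together 411 lower. Both had 1 residual degree of freedom and rested on the spread pooled over genes.

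The next 2 settings were chosen after seeing the data. With genes of under 10% shared reads only, 7 were lower in the NOD age comparison, 5 higher in that of B6, 86 higher and 95 lower in NOD against B6 at week 4, 321 and 65 at the later age, and 287 and 20 in the difference of the age changes, 93 and 54 lay above and below both B6 libraries, and the strain test called 121 and 70. With the GC and length trend removed, 20 were lower in the B6 age comparison, 105 higher in NOD against B6 at week 4, 138 higher at the later age and 105 higher in the difference of the age changes, and 96 lay above both B6 libraries. Fewer than 80.0% of the 2-fold different genes in both NOD against B6 comparisons had a GC value, so that these checks are void: at week 4, 100 of the 198 higher genes had one and 99 of them stayed 2-fold higher.

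Leaving out each library in turn, the strain test called 264 to 2919 genes higher and 146 to 452 lower, with the lone library of a strain taken to vary like the other strain. The genes above both B6 libraries, or the single one left, numbered 255 to 501 and those below 152 to 184. Camera with an estimated correlation was run on all 4 libraries only, where it called 0 lists. With age class as a block Kit, Hhex, Cd4 and Xist became called, on 1 residual degree of freedom. The p-values there rested on the spread pooled over genes, with a limma adjusted p of 1.85e-148 for H2-T3. Hhex was at RPKM 1.69 and 0.64 in B6 and 0.68 and 6.5 in NOD. Its call therefore shows no strain difference common to both ages. Leaving out a library also changed the calls of Kit, Hhex, Cd4, Lyl1, Tcf7, Cd3e, Notch1, Myc and Xist, with 1 library left in a strain. Nnt was no longer called without either NOD library. Depth limits genes of few reads: Lmo2, Hhex and Sfpi1 in the libraries where they were lowest have wide counting intervals.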

Other observations

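Few genes changed with age in the same direction in both strains. After TMM rescaling, over the 9028 genes with RPKM of 5 or more in any of the 4 libraries, 65 genes were 2-fold higher at the later age in NOD and 70 in B6, with 5 in common where 0.504 would be by independence. Among the 5 were the metallothionein genes Mt1 and Mt2, which bind zinc and respond to metals and glucocorticoids, and Mef2c, and the other two were unannotated gene models. The haemoglobin genes Hba-a1 and Hbb-b1 were 2-fold lower in both, of 13 genes in NOD and 61 in B6. Their values are uncertain, with shares of shared reads of up to 98% and 92% in the NOD libraries. In the opposite direction, Ddx3y, Eif2s3y, Ndg1 and Rmrp were lower in NOD and higher in B6. The changes of the Y-linked Ddx3y and Eif2s3y cannot be told apart from a different mix of the sexes in these libraries. The imprinted gene H19 had RPKM of 720.3 in B6 week 4, 363.9 in B6 week 7, 388.1 in NOD week 4 and 116 in NOD week 6.5. B2m, the light chain gene of MHC class I, was at 1319, 1461, 545.1 and 612.2 in the same order.

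The test on reads of one family placed on another copy, and the versions of the test on lost reads other than that with TMM rescaling, were chosen only after the results had been seen. Among 245 families of a gene and its numbered pseudogenes, 17 genes differed 2-fold between the strains. The median absolute log2 difference of these families was 0.937 for the totals, against 1.46 for totals with the pseudogenes held at their B6 level. Reads of the pseudogenes went the opposite way by 50% or more of the change of the gene in 6 of the 17: Rps18, for example, had 631.7 and 416.6 reads in B6 and 38.4 and 37.0 in NOD, scaled to depth, while its 5 pseudogenes had 60.9 and 50.55 in B6 and 500.1 and 502.7 in NOD. Reads placed on another copy are a candidate explanation for families such as Rps18, Rps24 and Ndufs5. The totals of Tpd52, Gapdh and Rpl29 still differed by -4.50, -3.55 and -5.57, but copies without a pseudogene number were not counted, so that for these genes and for the calls as a whole the test does not decide.

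Loss of NOD reads through sequence differences from the B6 reference was not excluded. Of the calls with under 10% shared reads, 43.97% of 307 (95% interval 38.3% to 49.7%) were lower in NOD after TMM rescaling, but 51.2% of 375 (46.0% to 56.4%) with the GC and length trend removed and 54.5% of 231 (47.9% to 61.1%) without B6 week 7. Haplotype blocks that differ between the strains are a candidate explanation. The 7050 annotated genes with under 10% shared reads were ordered by assembly GRCm38.p6, with all other genes left out. In that order 15 pairs of called genes were adjacent, where shuffling gave a mean of 5.89 (permutation p = 0.0007). Other genes can lie between the members of a pair. Such pairs included Tcte2 and Mllt4, Syne2 and Esr2, and H2-Ab1 and Notch4. The shuffling does not separate such blocks from reads of antisense neighbours, which could not be told apart here. Whether single genes differ through regulatory variants, deletions or copy number stays open, since no genome sequence of NOD was used here.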
